A study of Arabidopsis thaliana with 4 samples.

How the data were processed

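Poly(A) RNA was measured in hypocotyls of 5-day-old dark-grown Arabidopsis seedlings raised on MS medium at 22 °C, in 2 wild type Col-0 and 2 shr-2 libraries. The series' design text calls them biological duplicates. Per the labels' protocols, RNA was extracted with TRI reagent, cleaned on RNeasy columns and made into libraries with a TruSeq stranded mRNA kit, which keeps the strand of the transcript. Whether the counting used the strand is not given in the sources used here. Libraries were assigned to groups by their titles. Other label fields disagree with the titles, namely the genotype field of the mutant libraries and the tissue field of all 4 libraries, and levels of SHR, SCL28 and root markers are reported as a check.

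Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.13 and Cuffdiff 2.2.0 were used with the TAIR10 genome, and per the file headers the gene models were Araport11. The authors deposited FPKM values, fragment counts scaled to transcript length and to the mapped fragments of the library, for each gene and library. The table of the authors' comparison holds mean FPKM per genotype, a log2 fold change, an unsigned fold (ratio) of the larger over the smaller mean, a test statistic (score), and p-values with q-values from Cuffdiff. These deposited values are quoted as the authors' and were not recomputed. No read counts were used, so no count-based test was made. FPKM makes libraries relative to their own totals, so a change in total RNA per cell is not seen, and any further scaling that Cuffdiff applied between libraries is not given in the sources used here. A value of 0 means that the table lists the gene at 0, and 6956 of the 32538 genes were listed at 0 in all 4 libraries.

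The authors' loci were matched to the TAIR10.1 annotation by gene identifier. All 32538 genes matched, the deposited locus contained the annotated gene for 99.98% and equalled it for 71.72%. Coordinates in the text are those of TAIR10.1, counted from 1, and each value is for a whole gene, not for an exon. Named genes were compared with all transcripts by blastn 2.17.0, and 6 of 142 had a copy of at least 90% identity over at least 50% of their length. Of the 142, 34 overlap another gene model on either strand, and for these the assignment of reads is uncertain. Antisense pairs can be told apart only if the counting used the strand. PHS2 overlaps its neighbour on the same strand, where strand does not help.

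FPKM values were converted to log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries were kept, and SHR was kept whatever its mean, which left 19920 genes. Both genotypes entered one limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a mean-variance trend), 2-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit had 2 residual degrees of freedom and a prior worth 3.02. Fold changes are on the log2(FPKM + 1) scale, which understates the change of lowly expressed genes. Values are means ± SD over 2 libraries.

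Gene lists for ground tissue, cell wall, hormones, light, metabolism, stress and the cell types that a hypocotyl sample could hold were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. There were 37 lists with 590 entries, of which 583 paired a symbol with its identifier and were used and 7 were left out. The 35 lists with at least 5 measured members were tested with camera, with a preset correlation of 0.01 between genes, which compares a list with the other genes. An estimated correlation was an alternative. So was fry, which tests whether the genes of a list move, on balance, in one direction and does not compare them with other genes. With an estimated correlation 0 of the 35 lists passed, where camera with the preset value gave 13 and fry 17, and fry's test of change in either direction gave 32. With 4 libraries the correlation is estimated from 2 residual degrees of freedom.

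The named genes were SHR, SCR and SCL28, then the 10 largest increases and 10 largest decreases among called genes whose libraries separate by genotype, then up to 4 called members with the smallest adjusted p of each list, or up to 2 of the highest mean FPKM where none was called. A few members outside this rule are named where they went against their list or where the count was small (CIF1, HRE1, IAA20 and NRT2.1) or where a near-identical copy went the other way (PHT1-2), and were chosen after their values were seen.

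Depth was estimated from the values. A step in the lowest values, the worth of 1 fragment, was taken as their median within a fixed narrow window, scaled to transcript length. It came to 0.0417 to 0.0436 FPKM in a transcript of 1 kb. The window bounds this median, so similar values in all libraries do not show equal depth. Taken as it stands, the median implies 23437255 and 23983950 fragments in the wild-type libraries and 23319421 and 22960570 in the shr-2 libraries. At such a depth a value of 0.1 FPKM in a transcript of 1 kb rests on a few fragments.

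The fit was tested on simulated log2 values for 19920 genes with known changes. The noise was normal, independent between genes, and had the variances of the fit itself. The simulation thus follows the model of the fit and does not show its error rate in the real libraries. With 5000 changed genes, 71.06% were recovered at a log2 change of 0.5, 98.66% at 1 and 99.76% at 2, with 3.61%, 3.73% and 3.70% false calls. With 200 changed genes, 0% were recovered at 0.5, 87.98% at 1 and 99.4% at 2. The share of calls that were false was 100%, 9.00% and 8.87%, above the nominal 5%.

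The alternatives were leaving out each library in turn, pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-of-ratios and quantile scaling, a replicate block, other variance priors, a fold threshold and the other set tests. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for tables and draws. With 2 libraries per genotype, samples far from their group cannot be identified by a rank or gap test, and none was left out.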

Results

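Messenger RNA was sequenced from hypocotyls of Arabidopsis thaliana seedlings that had been germinated for 24 hours and then kept in darkness, and that were 5 days old when the hypocotyls were excised. The hypocotyl is the seedling stem below the cotyledons, which elongates strongly in the dark. Wild type Col-0, the reference accession, gave 2 libraries, and shr-2, a mutant of SHORT-ROOT (SHR), gave 2 libraries. SHR is a GRAS-family transcription factor that, together with SCARECROW (SCR), patterns the ground tissue and specifies the endodermis, the cell layer that surrounds the vascular tissue. The series compared the mutant with the wild type in this organ. The deposited values were FPKM, fragment counts scaled to transcript length and library size, for 32538 genes. A single fragment in a transcript of 1 kb was worth an estimated 0.0417 to 0.0436 FPKM. This estimate is bounded by the window searched and does not show whether the libraries were equally deep. Replicate libraries correlated across genes at Pearson r = 0.984 in the wild type and 0.981 in shr-2, and libraries of different genotype at 0.900 to 0.911. The first principal component held 83.0% of the variance.

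SHR transcripts were read first as a check of the labels. SHR (AT4G37650, chromosome 4, 17691687 to 17693859 in TAIR10.1) stood at 28.7 ± 0.396 FPKM (SD, n = 2) in the wild type and 3.01 ± 0.625 FPKM (n = 2) in shr-2. Its log2 fold change of FPKM + 1 was -2.90 with a standard error of 0.14 (limma, adjusted p = 0.00049). SCR (AT3G54220, chromosome 3, 20069987 to 20072878), the partner and transcriptional target of SHR, fell from 24.1 ± 1.03 to 7.87 ± 1.37 FPKM (limma, log2 fold change -1.51, adjusted p = 0.00248). A genotype field of the shr-2 libraries names an overexpressor of SCL28, another GRAS-family gene, whereas their titles and source name the shr mutant. SCL28 (AT1G63100) read 5.12 ± 0.168 FPKM in the wild type and 5.69 ± 0.168 in the mutant, a log2 fold change of 0.13 that did not pass the test (limma, adjusted p = 0.412). A tissue field names the root tip, whereas the title of the series and the growth protocol name the hypocotyl. Of 17 markers of the root meristem, root cap and root hairs, 0 reached a mean of 1 FPKM, and the highest value in any library was 0.671 FPKM, for NRT2.1. The groups were taken from the titles before any value was examined, and these levels go with the titles rather than with the other fields.

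Of 19920 genes with a mean of at least 1 FPKM, 5503 (27.6%) differed between shr-2 and the wild type, 2778 higher and 2725 lower in the mutant (limma, Benjamini-Hochberg adjusted p under 0.05). Among them, 863 were higher and 953 lower by a log2 fold change of at least 1. Protein-coding genes made up 5220 of the 5503. In the authors' deposited table, 5420 of 21844 genes with a completed test were called, 2761 higher and 2659 lower in shr-2. In all 5503 genes called here, both libraries of a genotype lay above both of the other. Both analyses called 4291 genes, and all 4291 had the same direction. That direction could not differ, since the authors' fold changes are of means of the same FPKM values. A further 1212 were called here and not in the authors' deposited table, and 764 of the genes tested here were called only there. Leaving out a library could not reverse the direction of a call either, since the genotypes do not overlap in these genes. The count of calls fell when a library was left out. It was 2058 without wild-type replicate 1, 2266 without wild-type replicate 2, 3434 without shr-2 replicate 2 and 3843 without shr-2 replicate 1, and no call changed direction.

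The largest increases included transcripts that were nearly absent from wild-type hypocotyls. AT3G06955, annotated as a long non-coding RNA (chromosome 3, 16498192 to 16498394), went from 3.13 ± 0.455 to 1019.8 ± 37.0 FPKM. ESP (AT1G54040), the epithiospecifier protein that directs glucosinolate breakdown toward nitriles, went from 0.106 ± 0.0411 to 111 ± 16.4 FPKM (limma, log2 fold change 6.66, SE 0.13, adjusted p = 0.000189). S-ACP-DES6 (AT1G43800), an acyl carrier protein desaturase, rose from 0.583 ± 0.049 to 78.8 ± 25.9 FPKM. ELIP2 (AT4G14690), an early light-induced chloroplast protein, rose from 1.75 ± 0.301 to 105 ± 24.6 FPKM, and ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, from 21.8 ± 3.35 to 720.1 ± 95.5 FPKM. The non-coding AT2G15555 rose from 0.119 ± 0.168 to 161 ± 17.8 FPKM. MIR398B (AT5G14545), the precursor of a microRNA that targets copper/zinc superoxide dismutases, was listed at 0 in both wild-type libraries and at 55.5 and 50.9 FPKM in the mutant libraries. AT2G05915 was also listed at 0 in both wild-type libraries, and at 132 and 136 FPKM in shr-2. AT2G05914, which overlaps it on the opposite strand, rose from 0.540 ± 0.108 to 193 ± 39.9 FPKM, and the reads of these 2 models can be told apart only if the counting used strand. AT2G11271 was at 18 and 0 FPKM in the wild-type libraries and at 492 and 527 FPKM in shr-2. It was the least secure of the 10 (limma, adjusted p = 0.0206), and its call was lost without shr-2 replicate 1 (0.0522) or replicate 2 (0.0582). In the authors' deposited table AT2G15555, AT2G05915, MIR398B and AT2G11271 were not called, with q-values of 0.346, 0.341, 0.503 and 0.511. MIR398B is 96.55% identical to the precursor gene AT5G14565 and overlaps AT5G14550 on the opposite strand, so the assignment of its reads is uncertain. MIR398B (chromosome 5, 4691022 to 4691137) and AT2G11271 (chromosome 2, 4485414 to 4485539) are short models, in which a fragment is worth more FPKM than in 1 kb. The short models AT1G04227 and SNOR108 read 208 and 128 FPKM in shr-2 replicate 1 and 0 in replicate 2. Values of such short models may thus rest on few fragments.

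The largest decreases included 2 genes of the fixed Casparian strip list. The Casparian strip is the lignin-based barrier that the endodermis builds into its walls. CASP1 (AT2G36100, chromosome 2, 15159591 to 15160799), a membrane protein that marks the site of the Casparian strip, fell from 130.1 ± 22.9 to 0.425 ± 0.501 FPKM (limma, log2 fold change -6.56, SE 0.27, adjusted p = 0.00033). CASP5 (AT5G15290) fell from 130.2 ± 22.4 to 0.456 ± 0.186 FPKM. The uclacyanin UCC1 (AT2G32300) went from 155 ± 38.3 to 0.528 ± 0.198, the peroxidase PER39 (AT4G11290) from 141 ± 17 to 0.516 ± 0.420 and the dirigent protein DIR24 (AT3G55230) from 123 ± 17.1 to 0.328 ± 0.292 FPKM. ATHSD2 (AT3G47350), a hydroxysteroid dehydrogenase, went from 131 ± 10.3 to 0.273 ± 0.330 FPKM. AT5G46900 showed the largest fall on the log2 scale of FPKM + 1, from 267 ± 51.0 to 0.940 ± 0.668 FPKM, and is 94.49% identical to AT5G46890, so its reads are uncertain. AT1G30750 (111 ± 19.8 to 0.315 ± 0.446 FPKM), AT5G26270 (91.3 ± 21.2 to 0.0828 ± 0.117 FPKM) and AT5G28919 (86.9 ± 14.0 to 0.0579 ± 0.0818 FPKM) completed the 10. The authors' deposited table lists CASP1 as 306-fold lower but did not call it (q = 0.285), nor AT5G26270 (0.516) and AT5G28919 (0.414). Mutant levels under 1 FPKM rest on few fragments, and the added pseudocount makes these fold changes smaller than the ratio of the means.

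Genes of the ground tissue and of the endodermal barrier fell together. Of 10 measured SHR/SCR ground-tissue regulators, 7 fell, 0 rose and 3 did not pass, with 9 lower when adjusted over the list alone (median log2 fold change -1.01, camera adjusted p = 3.9e-05). The adjusted p was 0.499 with an estimated correlation. Besides SHR and SCR these included MYB36 (AT5G57620), the transcription factor that switches on Casparian strip genes, which fell from 19.1 ± 0.612 to 0.112 ± 0.0649 FPKM, and the zinc-finger partner JKD (AT5G03150), which fell from 54.5 ± 8.36 to 20.7 ± 0.419 FPKM. The list shares MYB36 with the Casparian strip list, and SHR itself is the mutated gene. Of 11 measured genes of Casparian strip formation, 8 fell, 1 rose and 2 did not pass, the same counts as adjusted over the list alone. Their median log2 fold change was -4.29 (camera adjusted p = 2.1e-06, and adjusted p = 0.499 with an estimated correlation). PER64 (AT5G42180), a peroxidase of the strip, fell from 70.1 ± 3.0 to 0.395 ± 0.281 FPKM, and CASP4 (AT5G06200) from 20.6 ± 2.69 to 0.104 ± 0.0613 FPKM. The authors' deposited table did not call PER64 (q = 0.381) or CASP4 (0.182). The member that rose, at adjusted p = 0.0463, was CIF1, a peptide that signals to the barrier, and it did not pass with shr-2 replicate 2 or either wild-type library left out. The number that fell was 8 whichever library was left out. Of 5 measured suberin genes, 1 rose and 2 fell (camera adjusted p = 0.517), and 1 fell with shr-2 replicate 2 or either wild-type library left out. HHT1 (AT5G41040), a feruloyl transferase of suberin, fell from 7.01 ± 0.758 to 0.938 ± 0.0486 FPKM, and KCS2 (AT1G04220), a fatty acid elongase, rose from 9.02 ± 1.40 to 32.1 ± 5.80 FPKM.

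**Figure D1:**
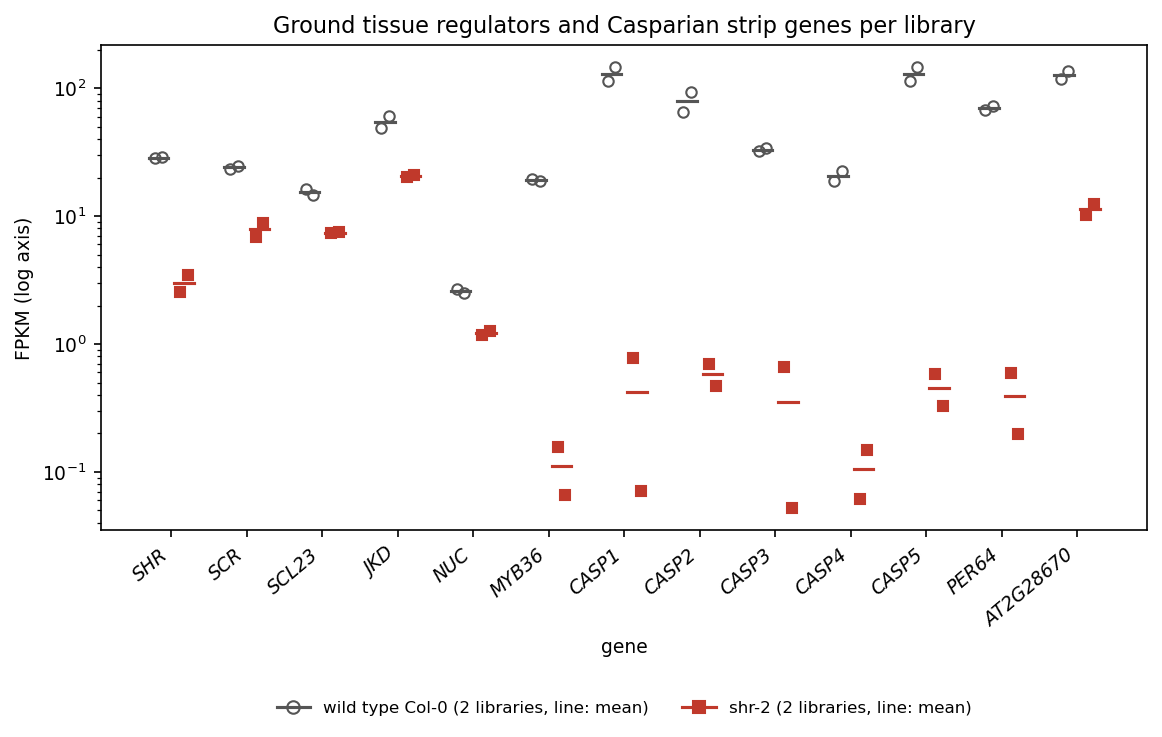
FPKM of ground tissue regulators and Casparian strip genes in each library, on a log axis, with 2 wild-type libraries (open circles) and 2 shr-2 libraries (filled squares) per gene and lines at the means. CASP1 lies at 130.1 FPKM in the wild type and 0.425 in shr-2, whereas SCR lies at 24.1 and 7.87.

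Genes of starch turnover and of the chloroplast rose in shr-2. Of 24 measured starch genes, 17 rose, 0 fell and 7 did not pass, with 18 higher when adjusted over the list alone (median log2 fold change 0.62, camera adjusted p = 1.2e-07, and adjusted p = 0.499 with an estimated correlation). They include enzymes of synthesis and of breakdown. GBSS1 (AT1G32900), the granule-bound starch synthase, rose from 1.12 ± 0.0306 to 7.78 ± 0.210 FPKM, and plastid phosphoglucomutase PGMP (AT5G51820), which feeds starch synthesis, from 21.9 ± 0.466 to 61.7 ± 1.42 FPKM. On the side of breakdown, the glucan phosphorylase PHS2 (AT3G46970) rose from 10.5 ± 0.157 to 29.1 ± 0.798 FPKM and the glucan, water dikinase GWD1 (AT1G10760) from 18.6 ± 0.114 to 39.1 ± 0.893 FPKM. PHS2 overlaps AT3G46980 on the same strand, so reads of the shared stretch are uncertain between them. The count of starch genes was 9 without wild-type replicate 1 and 10 without wild-type replicate 2. Of 18 genes of the light-harvesting antenna and the Rubisco small subunit, 11 rose, 0 fell and 7 did not pass, with 13 higher when adjusted over the list alone (median log2 fold change 0.99, camera adjusted p = 2.0e-06). The adjusted p was 0.522 with an estimated correlation, and the count was 6 without wild-type replicate 1 and 7 without wild-type replicate 2. RBCS-1B (AT5G38430) rose from 12.1 ± 1.18 to 92.7 ± 17 FPKM. The neighbouring small-subunit genes AT5G38410 (199.7 ± 5.58 to 807 ± 82.4 FPKM) and RBCS-2B (649 ± 9.42 to 1929 ± 92.6 FPKM) are up to 95.14% identical to each other, RBCS-1A or RBCS-1B, so the split of reads among these genes, RBCS-1B included, is uncertain. Of 13 seed and cotyledon genes fixed as markers of carried-over seed material, 4 had a mean of at least 1 FPKM, too few for a set test. The glyoxylate cycle enzymes ICL and MLS (malate synthase, AT5G03860, 3.48 ± 0.120 to 86.1 ± 15.8 FPKM) rose, as did PCKA (phosphoenolpyruvate carboxykinase, AT4G37870, 550.0 ± 27.6 to 786 ± 46.5 FPKM), whose call was lost whichever library was left out (adjusted p 0.0746 to 0.227). Seed storage and oil body transcripts stayed at or below 1.32 FPKM in every library. Of 9 measured regulators of leaf polarity and growth, a list written after the main result, 3 rose and 1 fell, with a median log2 fold change of 0.34.

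Flavonoid, fermentation and phosphate-starvation genes also rose. Of 7 measured flavonoid genes, 6 rose, 0 fell and 1 did not pass, with 7 higher when adjusted over the list alone (median log2 fold change 2.05, camera adjusted p = 6.8e-06, and adjusted p = 0.499 with an estimated correlation). CHS (AT5G13930), chalcone synthase at the entry to the pathway, rose from 6.0 ± 0.425 to 59.0 ± 4.67 FPKM (limma, SE 0.11 on the log2 scale, adjusted p = 0.00022), FLS1 (AT5G08640), flavonol synthase, from 1.39 ± 0.332 to 15.9 ± 0.425 FPKM, and MYB75 (AT1G56650), an activator of anthocyanin genes, from 1.66 ± 0.00663 to 7.06 ± 0.222 FPKM. Of 13 monolignol genes, 7 rose, 1 fell and 5 did not pass, with 8 higher and 1 lower when adjusted over the list alone (median log2 fold change 0.46, camera adjusted p = 0.0064, and adjusted p = 0.522 with an estimated correlation). OMT1 (AT5G54160), a methyltransferase, rose from 132 ± 10.0 to 237 ± 21.3 FPKM, a call lost without wild-type replicate 1 (adjusted p = 0.0723) or replicate 2 (0.0505). The number of monolignol genes called higher was 0 with either wild-type library left out and 2 without shr-2 replicate 2, and the number called lower was 0 whichever library was left out. All 10 measured hypoxia and fermentation genes changed, 9 upward and 1 downward, also when adjusted over the list alone (median log2 fold change 1.40, camera adjusted p = 6.6e-06, and adjusted p = 0.499 with an estimated correlation). Alcohol dehydrogenase ADH1 (AT1G77120) rose from 1.86 ± 0.192 to 17 ± 1.8 FPKM, the haemoglobin AHB1 (AT2G16060) from 7.89 ± 0.448 to 64.9 ± 11.2 FPKM and sucrose synthase SUS1 (AT5G20830) from 3.6 ± 0.192 to 20.9 ± 0.837 FPKM. The exception was HRE1, an ethylene response factor of the low-oxygen response, which fell from 3.87 ± 0.0808 to 2.56 ± 0.0357 FPKM and was not called when any library was left out. Of 11 phosphate-starvation genes, 7 rose, 1 fell and 3 did not pass, with 8 higher and 1 lower when adjusted over the list alone (median log2 fold change 0.66, camera adjusted p = 0.015, and adjusted p = 0.499 with an estimated correlation). The sulfolipid enzyme SQD1 (AT4G33030) rose from 51.9 ± 1.23 to 149 ± 5.77 FPKM and SPX1 (AT5G20150) from 37.7 ± 6.42 to 114 ± 12.2 FPKM, whereas the phosphate transporter PHT1-1 (AT5G43350), fell from 49.9 ± 8.75 to 13.9 ± 2.26 FPKM. It is up to 97.72% identical to 2 neighbouring copies, of which PHT1-2 went the other way, from 0.132 and 0.0635 FPKM in the wild type to 5.17 and 6.71 in shr-2, so the split of reads is uncertain. The count of phosphate-starvation genes that rose was 4 without wild-type replicate 1.

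Genes that mark sugar starvation fell. Of 9 measured genes of the sugar-starvation and dark-inducible list, 7 fell, 0 rose and 2 did not pass, with 8 lower when adjusted over the list alone (median log2 fold change -1.25, camera adjusted p = 6.6e-06, and adjusted p = 0.499 with an estimated correlation). BGLU30 (AT3G60140), a beta-glucosidase also known as DIN2, fell from 71.5 ± 18.3 to 3.6 ± 0.152 FPKM (limma, log2 fold change -3.96, SE 0.19, adjusted p = 0.00049). ASN1 (AT3G47340), asparagine synthetase, fell from 212 ± 23.2 to 46.5 ± 4.21 FPKM, and BCAT2 (AT1G10070), an enzyme of branched-chain amino acid breakdown, from 273 ± 31.3 to 92.5 ± 1.82 FPKM.

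**Figure D2:**
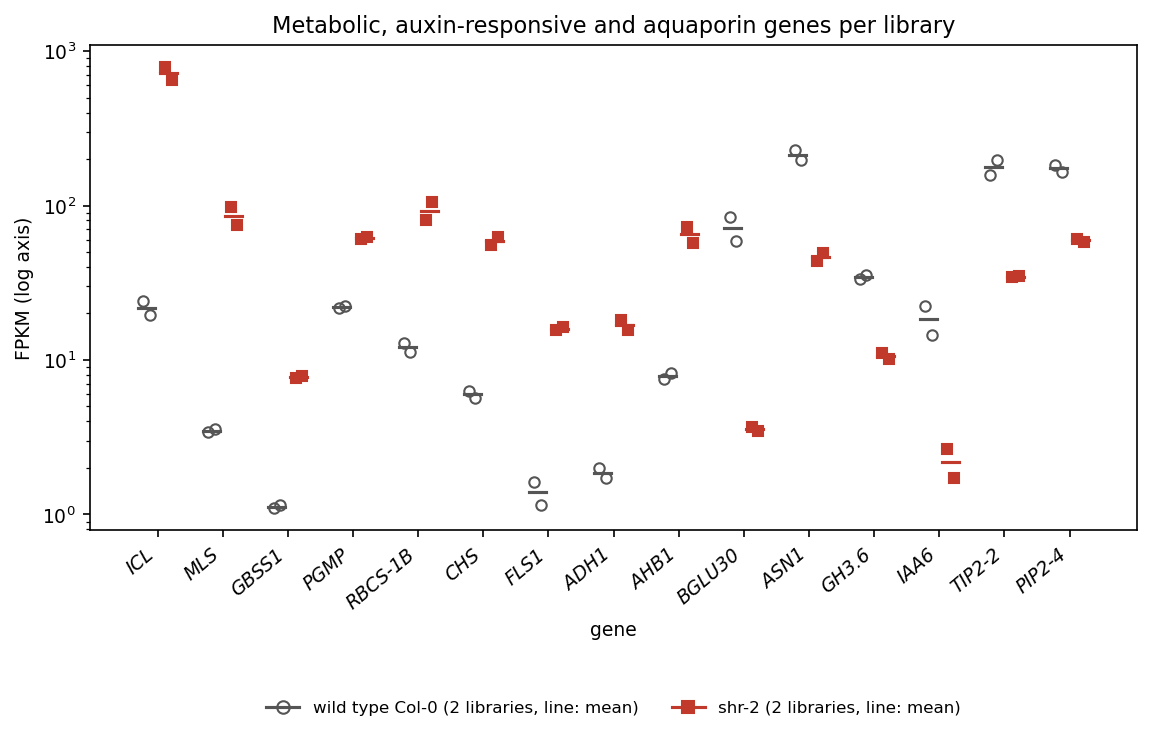
FPKM of metabolic, auxin-responsive and aquaporin genes in each library, on a log axis, with 2 wild-type libraries (open circles) and 2 shr-2 libraries (filled squares) per gene and lines at the means. ICL rises from 21.8 to 720.1 FPKM and BGLU30 falls from 71.5 to 3.6 FPKM.

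Auxin-responsive, jasmonate and aquaporin genes fell. Of 24 measured early auxin response genes, 16 fell, 1 rose and 7 did not pass, with 18 lower and 1 higher when adjusted over the list alone (median log2 fold change -0.92, camera adjusted p = 3.3e-07, and adjusted p = 0.522 with an estimated correlation). The auxin-conjugating enzymes GH3.6 (AT5G54510, 34.5 ± 1.54 to 10.6 ± 0.731 FPKM) and GH3.5 (AT4G27260, 81.2 ± 4.64 to 36.9 ± 1.76 FPKM) and the Aux/IAA repressor IAA6 (AT1G52830, 18.4 ± 5.46 to 2.2 ± 0.657 FPKM) were among them, and IAA20 was the member that rose. The number that fell was 6 without wild-type replicate 1, and the number that rose was 0 with either wild-type library left out. Of 20 aquaporins, 14 fell, 2 rose and 4 did not pass, with 15 lower and 3 higher when adjusted over the list alone (median log2 fold change -0.98, camera adjusted p = 4.8e-05, and adjusted p = 0.522 with an estimated correlation). The tonoplast TIP2-2 (AT4G17340) fell from 176 ± 27.7 to 34.7 ± 0.410 FPKM and the plasma membrane PIP2-4 (AT5G60660) from 174 ± 11.4 to 59.4 ± 2.03 FPKM, whereas TIP4-1 (AT2G25810) rose from 4.41 ± 1.00 to 29.4 ± 5.16 FPKM. The number of aquaporins that fell was 8 with either wild-type library left out. Of 10 jasmonate genes, 7 fell, 1 rose and 2 did not pass, also when adjusted over the list alone (median log2 fold change -0.67, camera adjusted p = 0.00054, and adjusted p = 0.522 with an estimated correlation). The vegetative storage proteins VSP1 (AT5G24780, 9.72 ± 0.242 to 2.05 ± 0.277 FPKM) and VSP2 (AT5G24770, 7.45 ± 0.452 to 0.800 ± 0.251 FPKM) showed the smallest adjusted p. The number that fell was 3 with either wild-type library left out, and the number that rose was 0 there and without shr-2 replicate 2. Of 19 brassinosteroid genes, 4 fell and 15 did not pass, with 8 lower and 1 higher when adjusted over the list alone (median log2 fold change -0.30, camera adjusted p = 0.029, and adjusted p = 0.499 with an estimated correlation). They were the receptor BRI1 (AT4G39400, 93.3 ± 1.74 to 63.4 ± 3.38 FPKM) and the biosynthetic enzymes ROT3, CYP90B1 and CYP85A2, and each of the 4 calls was lost with either wild-type library left out (adjusted p 0.0774 and 0.0837 for BRI1). This list did not pass without wild-type replicate 1 (camera adjusted p = 0.074) or shr-2 replicate 2 (0.056), which left 0 and 2 members called, and 1, another member, was called without wild-type replicate 2.

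**Figure D3:**
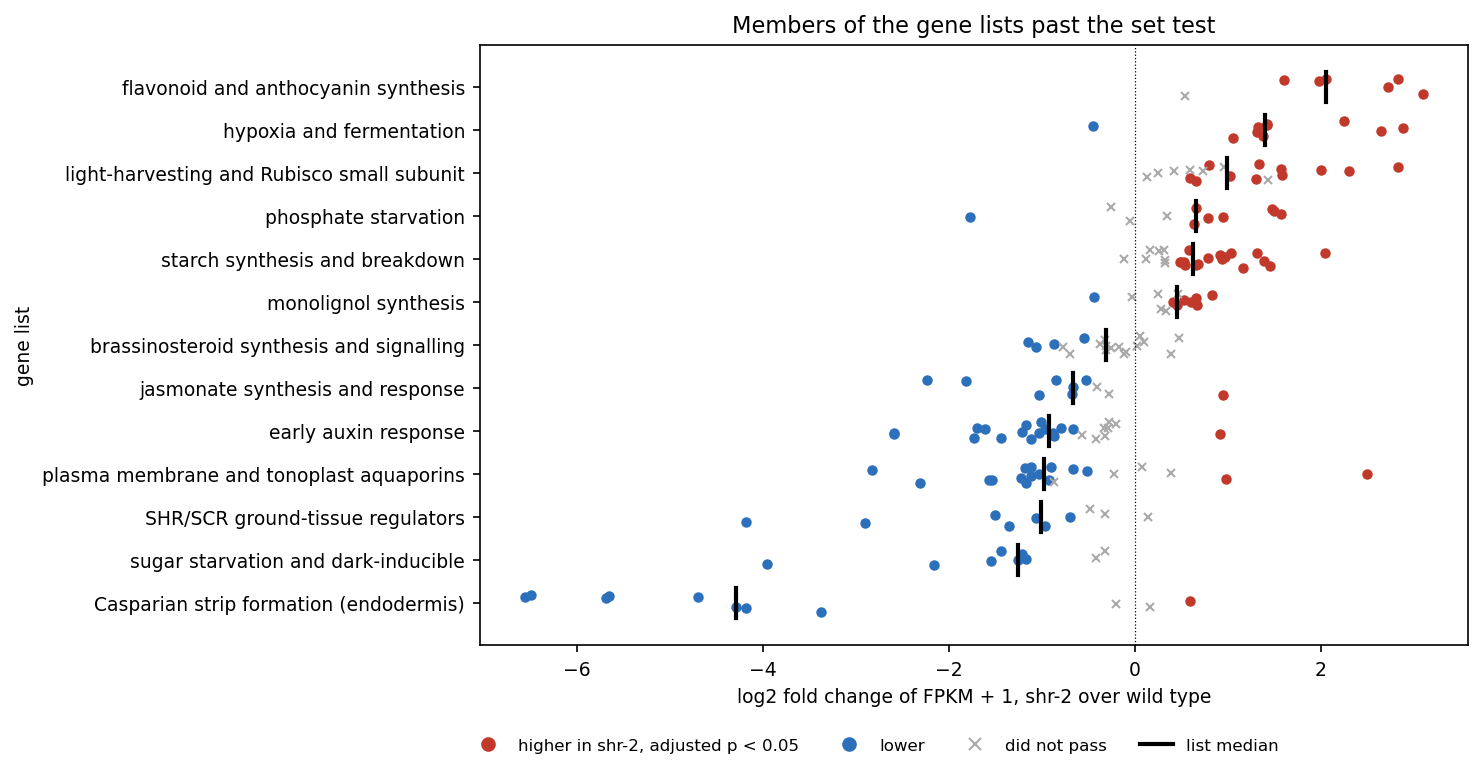
Log2 fold change of FPKM + 1, shr-2 over wild type, of each measured member of the 13 gene lists that passed the set test, in red where higher, in blue where lower and as grey crosses where the member did not pass, with black bars at list medians. Medians run from -4.29 for Casparian strip genes to 2.05 for flavonoid genes.

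Wall-loosening and wall-synthesis lists did not move one way. Of 20 expansins, 6 rose and 8 fell (camera adjusted p = 0.602). EXPB1 (AT2G20750) fell from 12.3 ± 0.129 to 4.83 ± 0.0795 FPKM and ATEXPA14 (AT5G56320) from 10.1 ± 1.41 to 3.07 ± 0.306 FPKM, whereas EXLB1 (AT4G17030) rose from 6.38 ± 0.597 to 12.9 ± 0.434 FPKM. Of 22 xyloglucan endotransglucosylase/hydrolases, 5 rose and 9 fell, with 10 lower when adjusted over the list alone (camera adjusted p = 0.488). XTH32 (AT2G36870) rose from 19.2 ± 1.66 to 53.6 ± 3.24 FPKM and XTH30 (AT1G32170) fell from 141 ± 13.4 to 50.3 ± 8.13 FPKM. Of 10 genes of primary-wall cellulose synthesis, 0 passed (camera adjusted p = 0.526), and the chitinase-like CTL1 (AT1G05850) read 660.5 ± 35.2 and 674 ± 52.5 FPKM. Of 22 secondary wall genes, 5 rose and 1 fell (camera adjusted p = 0.215). The one that fell, IRX7 (AT2G28110), a glycosyltransferase of xylan synthesis, went from 49.4 ± 1.94 to 10.1 ± 0.441 FPKM. With each library left out in turn, 1 to 4 expansins rose and 3 to 5 fell, 2 to 5 xyloglucan enzymes rose and 3 to 5 fell, and 0 to 2 secondary wall genes rose.

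Among the remaining hormone and signalling lists, none passed the set test. Of 22 gibberellin genes, 1 rose and 5 fell (camera adjusted p = 0.637). The one that rose, GA2OX7 (AT1G50960), inactivates gibberellin precursors and went from 0.151 ± 0.0921 to 2.71 ± 0.207 FPKM, and the gibberellin-induced GASA6 (AT1G74670) fell from 213 ± 12.7 to 101 ± 6.49 FPKM. Of 14 genes of auxin synthesis and transport, 6 fell and 0 rose (camera adjusted p = 0.061), among them PIN3 (AT1G70940), an efflux carrier, at 130.2 ± 16.6 and 76.7 ± 7.11 FPKM, whose call was lost without wild-type replicate 1 (adjusted p = 0.0855) or shr-2 replicate 2 (0.0605). That count of 6 was 2 without shr-2 replicate 1, 0 without shr-2 replicate 2 and 1 with either wild-type library left out. Of 9 shoot gravitropism genes, 1 rose and 4 fell (camera adjusted p = 0.194), with SGR5 (AT2G01940), a zinc-finger protein of endodermal gravity sensing, falling from 24.8 ± 0.0952 to 10.9 ± 0.591 FPKM. Of 13 cytokinin genes, 2 rose and 3 fell (camera adjusted p = 0.265), ARR5 (AT3G48100), a response regulator, falling from 78.3 ± 9.06 to 41.0 ± 2.31 FPKM. Of 17 genes of the abscisic acid list, 3 rose and 2 fell (camera adjusted p = 0.360), RD22 (AT5G25610) rising from 132 ± 7.58 to 267 ± 5.81 FPKM and RAB18 (AT5G66400) falling from 13.4 ± 2.40 to 4.81 ± 0.411 FPKM, the latter not called in the authors' deposited table (q = 0.0556). Of 9 ethylene genes, 1 rose and 1 fell (camera adjusted p = 0.488), and 0 rose and 0 to 2 fell with each library left out in turn. Of 16 light-signalling genes, 5 rose and 1 fell (camera adjusted p = 0.265). ELIP2 was the largest of the 5, and HFR1 (AT1G02340), a regulator of seedling growth in light, fell from 98.6 ± 22.8 to 38.8 ± 0.814 FPKM. With each library left out in turn, 1 to 3 gibberellin and 2 to 3 gravitropism genes fell, 0 to 2 cytokinin genes rose and 1 fell, 2 to 5 abscisic acid genes rose and 1 to 3 fell, and 2 to 7 light-signalling genes rose and 1 to 2 fell.

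Markers of other tissues, stress and the cell cycle completed the lists. Of 28 S-phase and mitosis genes, 0 rose and 2 fell (camera adjusted p = 0.721), CYCB1-4 (AT2G26760, 12.8 ± 0.456 to 7.11 ± 0.906 FPKM) and CDKB2-1 (not called in the authors' deposited table, q = 0.0574), and 0 were called with either wild-type library left out. Of 6 genes of the SCL28 and SIAMESE-type inhibitor list, 0 passed (camera adjusted p = 0.625), and 1 fell with either shr-2 library left out. SIM (AT5G04470) read 98.4 ± 30.2 and 59.4 ± 29.0 FPKM (limma, adjusted p = 0.205) and was called lower in the authors' deposited table (q = 0.0045), and SMR2 (AT1G08180) read 16.3 ± 3.66 and 18.5 ± 0.619 FPKM. Of 7 stomatal lineage genes, 2 rose and 0 fell (camera adjusted p = 0.055). These were the receptor-like TMM (AT1G80080, 3.19 ± 0.329 to 5.89 ± 0.268 FPKM) and SPCH (AT5G53210, 1.42 ± 0.182 to 3.27 ± 0.510 FPKM), and both calls were lost with shr-2 replicate 2 or either wild-type library left out. Of 12 phloem genes, 2 rose and 4 fell (camera adjusted p = 0.637), the sucrose exporter SWEET12 (AT5G23660) falling from 161 ± 0.301 to 95.5 ± 3.54 FPKM, though not called without wild-type replicate 1 (adjusted p = 0.0502). Of 7 procambium and HD-ZIP III genes, 1 rose (camera adjusted p = 0.240), and of 14 epidermis and cuticle genes 2 rose and 3 fell (camera adjusted p = 0.488). With each library left out in turn, 0 to 2 phloem genes rose and 0 to 2 fell, 0 to 1 procambium genes rose, and 0 to 3 epidermis genes rose and 0 to 2 fell. Of 12 glucosinolate genes, 4 rose and 4 fell (camera adjusted p = 0.720). BCAT4 (AT3G19710) and CYP83A1 (AT4G13770), which act in the methionine-derived branch, rose from 1.53 ± 0.0341 to 36.4 ± 6.47 FPKM and from 1.24 ± 0.278 to 10.6 ± 0.0496 FPKM. The myrosinase TGG2 (AT5G25980) fell from 4.75 ± 0.370 to 0.0886 ± 0.0375 FPKM. Of 13 immune genes, 4 rose and 3 fell (camera adjusted p = 0.526), CYP71B15 (AT3G26830) of camalexin synthesis rising from 1.59 ± 0.0211 to 8.36 ± 0.312 FPKM. Of 9 iron genes, 3 rose and 1 fell (camera adjusted p = 0.473), the nicotianamine synthase NAS1 (AT5G04950) rising from 1.27 ± 0.302 to 5.40 ± 0.698 FPKM. Of 5 heat-shock genes, 0 passed (camera adjusted p = 0.637). HSP90-1 (AT5G52640) read 9.26 and 14.5 FPKM in the wild type, 12.1 in shr-2 replicate 1 and 52.6 in shr-2 replicate 2. Without shr-2 replicate 1, 3 heat-shock genes were called higher. With each library left out in turn, 2 to 3 glucosinolate genes rose and 1 to 2 fell, 1 to 5 immune genes rose and 0 to 2 fell, and 2 to 3 iron genes rose and 0 fell.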

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

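All alternatives reported here were chosen before the data were examined. No call among the 5503 changed direction under any of them. Only the scalings could have reversed one, since in all 5503 both libraries of a genotype lay above both of the other. SHR stayed lower in shr-2 with a log2 fold change between -3.22 (pseudocount of 0.1) and -2.07 (pseudocount of 5). The count of changed genes stayed within 1.5 times under other pseudocounts, filters, scalings and variance priors, from 4415 with a filter at 5 FPKM to 5646 with quantile scaling. With one library left out, where the lone library is assumed to vary like the other group, 2058 to 3843 genes were changed, 964 to 2053 higher and 1094 to 1799 lower. The lowest count came without wild-type replicate 1, and fewer samples give fewer calls. A log2 fold change of at least 1 as a further threshold left 1816 genes, 863 higher and 953 lower, by construction. With an estimated correlation between genes 0 of 35 lists passed, and the 2 residual degrees of freedom limit that estimate. With fry, gravitropism, auxin transport, ethylene, light signalling, stomata and glucosinolate genes passed as well (adjusted p 0.0117, 0.0343, 0.0337, 0.0337, 0.0208 and 0.0053), and monolignol and brassinosteroid genes no longer did (0.0581 and 0.0594). Auxin transport also passed without wild-type replicate 2 and without a filter, stomata without shr-2 replicate 2, without a filter and without a variance trend, suberin without a filter, and cytokinin with the filter at 5 FPKM. Of 141 named genes, 96 kept their side of the threshold without wild-type replicate 1, 99 without wild-type replicate 2, 125 without shr-2 replicate 1 and 114 without shr-2 replicate 2. HSP90-1 gained a call without shr-2 replicate 1, as SIM did without shr-2 replicate 2.

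With the replicate number as a block, 8729 genes were changed, 4486 higher and 4243 lower, and SIM and KOR gained calls (adjusted p 0.0050 and 0.038). The numbers are shared across genotypes, but no label says that they mark a shared batch, so the pairing is only a number. Differences between replicates correlated at r = 0.305 between the genotypes across genes. Ratios of low values fell on whole steps for 52.7% of genes in the pair numbered 1 and 21.3% in the pair numbered 2, against 9.44% to 15.3% in other pairs, a hint from the data and not from the design.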

Other observations

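All tests in this part were chosen after the main result was seen, and for the explanations weighed below what each outcome would mean was written before its value was known, except for the genome-segment and neighbouring-copy tests, the test without single-library genes and the comparison of microRNA genes with the MIR398B rise. A scan of 232 families of genes that share a symbol, in both directions (464 one-sided Fisher tests on calls among 19920 genes), gave 20 at an adjusted p under 0.05. Fisher's test counts the genes of a family as independent, so these p-values make no allowance for correlation between them. Of 11 PTAC genes, components of the plastid transcription machinery, 9 rose (adjusted p = 0.00019, median log2 fold change 0.74), as did 10 of 15 TIC genes of protein import into the plastid (adjusted p = 0.00049, median 0.52, 1 lower) and 8 of 11 CPN genes, plastid and mitochondrial chaperonins (adjusted p = 0.0015, median 0.69). Of 130 RPL ribosomal protein genes 34 rose (adjusted p = 0.0076, median 0.27), and 7 of 9 LTP lipid transfer protein genes did (adjusted p = 0.0022, median 1.27), with 1 RPL and 2 LTP genes lower. The RPS ribosomal protein genes did not pass, with 17 of 102 higher (Fisher, unadjusted p = 0.251) and 6 lower. Of the families that fell, 14 of 19 SAUR genes were lower (adjusted p = 2.1e-06, median -0.98), a family partly held by the auxin list. Of 42 PER class III peroxidases 18 were lower and 7 higher (adjusted p = 0.00049 for lower, median -0.17), and of 48 WRKY genes 15 were lower and 5 higher (adjusted p = 0.035 for lower, median -0.33). Of 152 CYP genes 39 were lower (adjusted p = 0.0034) and 32 higher (adjusted p = 0.157), a split with a median of 0.06.

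Several genes of copper homeostasis differed between the genotypes besides MIR398B. COPT2, a copper transporter, was at 0.0648 and 0 FPKM in the wild-type libraries and at 7.98 and 8.61 in shr-2. MIR398C (AT5G14565) was listed at 0 in all libraries except shr-2 replicate 2, at 59.3 FPKM, and did not pass (adjusted p = 0.302). It is the near-identical copy of MIR398B, so its reads are no separate evidence. FSD1, the iron superoxide dismutase that replaces the copper enzymes when copper is short, rose from 162 to 1293 FPKM, and CSD1 and CSD2, the copper/zinc enzymes that miR398 targets, fell from 296 to 188 and from 209 to 137 FPKM. COPT6, CCH and ARPN did not pass (adjusted p 0.710, 0.109 and 0.205). COPT2, MIR398B, MIR398C and MIR408 also belong to the set of genes found in one genotype that is weighed below.

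Chloroplast, starch and glyoxylate cycle transcripts rose together, and different amounts of another tissue and a different stage were the technical explanations weighed. Other technical explanations were not weighed. More cotyledon or leaf tissue in the mutant samples would raise leaf regulators, and their median log2 fold change was 0.3413, with 3 of 9 higher and 1 lower. Seedlings less advanced after germination would keep seed storage and oil body transcripts. Their median log2 difference was 0.4362 over 10 transcripts, 8 of them higher in shr-2. Most of the 10 rest on a few fragments at most, so this value decides nothing. The leaf value lies between what the explanation needs, at least 0.5, and what would exclude it, 0 or lower, so neither explanation could be told apart from a change within hypocotyl cells. The effect of the mutation on these genes is among the open explanations.

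A set of 161 genes had a mean above 5 FPKM in one genotype and under 0.5 FPKM in the other, 54 of them found in shr-2 and 107 in the wild type, and 21 of them (14 in shr-2) were listed at 0 in one library of the genotype in which they were found. Overlap with other gene models was argued against as the source, since 34.16% of the 161 overlap another gene and draws of other expressed genes gave a median of 34.78%. Genome segments of another accession in the mutant would put such genes side by side, and 38.51% had another within 100 kb, above the level that 2.5% of 1000 draws of expressed genes exceed (37.27%, median of draws 27.33%). With 1 gene kept of each set of similar sequences, 30.99% of 142 did, under the same level for draws thinned in the same way (34.51%, median 24.65%), so neighbouring copies that change together may account for the excess and segments remain open too. Without the 21 single-library genes the share was 35% of 140 (level for draws 33.57%, median 24.29%). Of the 161, 10 lay among the 140 expressed genes from 17000001 to 18000000 of chromosome 3 and 0 within 500 kb of SHR. An effect of the mutation on these genes was not weighed here and is open as well. SCR and JKD, ground-tissue regulators outside the set, also fell. What stays open here stays open for every gene of the set. Members found in shr-2 include ESP, AT2G15555, AT2G05915, MIR398B, MIR398C, MIR408, COPT2 and PHT1-2. Members found in the wild type include ATHSD2, DIR24, MYB36, PER64, CASP1, CASP4, CASP5, AT1G30750, AT5G26270 and AT5G28919.

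For the copper genes, a list of 15 members besides MIR398B, MIR398C and COPT2 was written before their values were looked at, and 10 had a mean of at least 1 FPKM. The 10 include MIR408, FSD1, CSD1, CSD2, COPT6, CCH and ARPN, named above, so the values given there are not separate evidence. Signed by the direction known for copper deficiency, their median log2 fold change was 0.7277, at percentile 99.99 of 10000 random lists matched on mean FPKM, and 7 of the 10 passed in that direction and 0 in the other. The random lists were not drawn as genes that change together, so the percentile makes no allowance for correlation among the copper genes. A general gain of microRNA precursors with a median log2 fold change of at least 1 was argued against. The 49 other microRNA genes had a median of 0.2423 (SD 1.63, bootstrap 95% interval of the median -0.23 to 0.93). Their largest value was 3.81, against 5.76 for MIR398B. MIR398B was picked as one of the largest increases of all genes, so that comparison decides nothing. A smaller general gain stays open with 10 higher and 2 lower. A copper deficiency response in shr-2 hypocotyls may account for the genes that passed, as a hypothesis that a measurement of copper would test. Whether such a response would follow from the mutation or from growth conditions was not tested.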
